A study of Homo sapiens with 9 samples.

How the data were processed

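Messenger RNA was measured by RNA sequencing in 9 libraries of human astrocytes, 3 from astrocytes cultured alone, 3 from astrocytes co-cultured with NCI-H82 cells and 3 from astrocytes co-cultured with NCI-H69 cells. Per the labels' protocols, frozen cells went to a commercial service for total RNA isolation, library preparation and Illumina sequencing. Whether the libraries keep strand, and how astrocytes were separated from tumour cells, is not given in the sources used here.

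Per the submitters' processing notes, the authors used Salmon 0.8.2, DESeq2 1.28.1 and the GRCh38 genome build. Per the file headers, each deposited file is a Salmon transcript table of 1 library with 175775 transcripts. The deposited estimated counts (expected counts) are Salmon's estimate of the reads from each transcript, and are neither whole numbers nor normalized. The deposited TPM values are length-adjusted abundances scaled by Salmon within each library, and were only checked to sum to the same total. Per the file headers, another column holds the effective transcript length in bases, which served only for a length offset among the alternatives.

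Transcripts were joined to genes through GENCODE release 29, which holds 168029 of them. A further 6869 transcripts were placed by gene symbol, and 877 were left out. Between 98.2% and 98.4% of the estimated reads of a library lay in transcripts of that annotation, 1.53% to 1.69% were placed by symbol and 0.103% to 0.133% could not be placed. Estimated counts were summed per gene and rounded to whole numbers. Totals ran from 13726481 to 18408912 estimated reads per library. Genes of the Y chromosome and the X-inactivation transcript were left out of every table. All replicate pairs differed by more than sampling noise, so each library counted as 1 sample. The labels do not say what a replicate number marks. Deviations of same-numbered libraries correlated at 0.496, 0.161 and 0.471 between astrocytes alone and with NCI-H82. They correlated from -0.249 to 0.338 between alone and NCI-H69 and from -0.091 to 0.322 between the co-cultures. Replicate 2 alone correlated better with replicate 1 with NCI-H82 (0.361). The highest value, 0.565, joined replicate 1 alone and replicate 2 with NCI-H69. Each library numbered 3, however, correlated best in both other groups with the library numbered 3, at 0.471, 0.338 and 0.307. The data thus link replicate 3 across the groups but do not settle a pairing for the other numbers.

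Genes were tested with edgeR 4.0.16 in R 4.3.3. The low-count filter of edgeR, with its minimum count of 10 and minimum total of 15, kept 14177 genes. TMM factors scaled the libraries, and a quasi-likelihood F test over all 9 libraries compared the 3 groups jointly and in pairs. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as passing. The common biological coefficient of variation was 0.328. CPM values are scaled by the TMM factors. Standard errors of log2 fold changes come from the same fit. For a group with 1 to 3 counts in total the fold is a ratio of counts with a 95% counting interval, and for a group with 0 counts it is a lower bound set at 3 counts over the group. These intervals and bounds cover counting error only.

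The 23 gene lists, with 547 entries, were fixed before the data were examined, and so were the tests, the alternatives and the rule for naming genes. Each list was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and the rotation test fry were alternatives. Genes were named by rule. In each pairwise comparison these were the 10 higher and 10 lower protein-coding genes with the largest log2 fold change that passed, had a mean of at least 5 CPM in the higher group and showed no overlap between the groups. Added to these were up to 4 members of each list with the smallest adjusted p, and a fixed panel of 16 genes. For the genes changed in both co-cultures, 5 higher and 5 lower genes were named.

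Shares of reads in mitochondrially encoded genes, ribosomal protein genes and the 20 most abundant genes were compared with exact two-sided permutation tests, which cannot give a p below 0.1 with 3 libraries against 3. Fold changes of both co-cultures share their control libraries, so their overlap was set beside 20 simulations without group differences. All 9 libraries, controls included, were drawn anew and independently of each other. Alternatives covered RLE and upper-quartile factors, no filter and a stricter filter, DESeq2 1.42.0, a transcript length offset, protein-coding genes alone, removal of mitochondrial genes, the replicate number as a block, fits of only the groups compared, a minimum log2 fold change of 1 and leaving out each replicate. A fit without 2 libraries that stood apart, and limma voom with library quality weights, were added after seeing the data.

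The edgeR step was tested on simulated data with known changes of 2-fold and 4-fold. With astrocytes alone against the NCI-H82 co-culture, it recovered 69.1% of 4-fold and 6.12% of 2-fold changes among 13989 genes tested. With the NCI-H69 co-culture against astrocytes alone, it recovered 68.7% and 7.29% among 13980 genes, and between the co-cultures 68.4% and 6.06% among 14012 genes.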

Results

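The transcriptome of human astrocytes was profiled after culture alone or in co-culture with NCI-H82 or NCI-H69 cells, both established small-cell lung cancer lines. The series concerns how this neuroendocrine cancer grows in the brain, and the co-cultures ask how astrocytes respond to its cells. Each of the 3 groups held 3 libraries, with 13726481 to 18408912 estimated reads per library and 16427 to 18091 genes with at least 1 read. Nothing in the labels says that replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. Values are TMM-scaled CPM as mean ± SD with n = 3 per group, and log2 fold changes carry their SE. Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Coordinates are 1-based positions on GRCh38.

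Culture condition separated the astrocytes at 668 of 14177 genes in the joint test of the 3 groups, and 2603 genes had an unadjusted p under 0.05. The first principal component held 36.9% of the variance and the next 27.9%. Replicate 3 of astrocytes alone and replicate 3 with NCI-H82 stood apart from their groups. Their mean correlation with the other replicates across genes was 0.930 and 0.917, against 0.948 or more for every other library. Mitochondrially encoded genes took 12.9% of the reads of that replicate alone and 10% of the reads of that NCI-H82 replicate. They took 2.76% and 5.09% in the other replicates alone, 3.81% and 4.75% in the other NCI-H82 replicates and 4.18% to 10.9% with NCI-H69. None of the 15 comparisons of depth and composition between groups reached an exact permutation p under 0.2, and their adjusted p was at least 0.964.

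**Figure D1:**
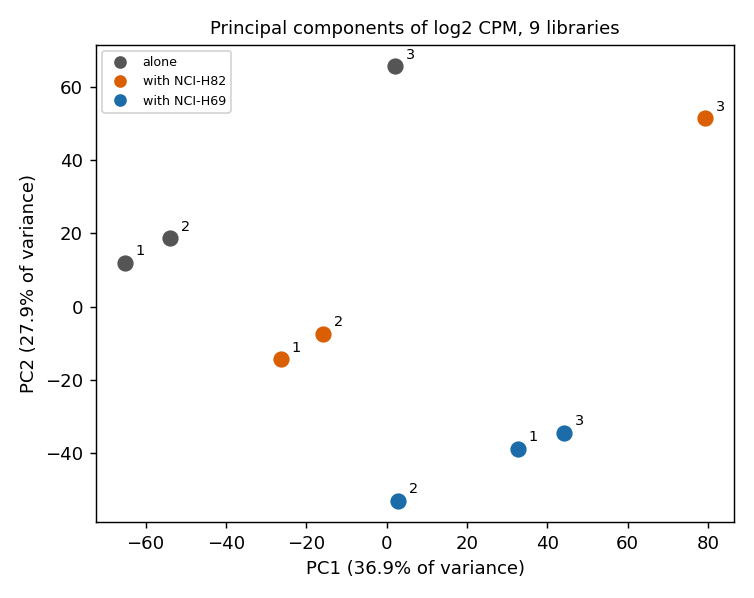
Each point is 1 of the 9 libraries on the first and second principal components of log2 CPM (axes unitless, 36.9% and 27.9% of the variance), coloured by group and numbered by replicate. Replicate 3 of astrocytes alone and replicate 3 with NCI-H82 lie far from the other replicates of their groups.

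Astrocytes cultured with NCI-H82 had higher levels of amino acid response genes and lower levels of sterol synthesis genes. ASNS, which encodes asparagine synthetase (ENSG00000070669.16, chromosome 7, 97852118 to 97872542), rose 28.9-fold from 14.2 ± 4.22 to 411 ± 368 CPM (log2 fold change 4.85 ± 0.61, adjusted p = 0.00916). CHAC1, an enzyme of glutathione breakdown (ENSG00000128965.12, chromosome 15, 40952962 to 40956519), rose 23.9-fold from 5.10 ± 0.458 to 122 ± 70.4 CPM (adjusted p = 0.00256). SQLE, the squalene epoxidase of sterol synthesis, fell from 144 ± 2.37 to 31.3 ± 11.0 CPM (log2 fold change -2.19 ± 0.27, adjusted p = 0.00909). In total 94 of 14177 genes passed, 49 higher and 45 lower, and 1575 had an unadjusted p under 0.05.

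Of the 22 members of the amino acid and unfolded protein stress list, 9 rose, none fell and 13 did not pass, and 15 were higher when adjusted over the list alone. The median log2 fold change of the list was 2.08 (camera adjusted p = 1.33e-15, but adjusted p = 0.165 with an estimated correlation). The transporter genes SLC7A5, for large neutral amino acids, and SLC7A11, for cystine, rose by 4.0 ± 0.45 and 3.40 ± 0.50 on the log2 scale. PSAT1, of serine synthesis, rose by 3.35 ± 0.37, and the pseudokinase gene TRIB3 by 4.37 ± 0.78. These were smaller without both libraries that stood apart, with ASNS at 4.07, SLC7A5 at 3.69, SLC7A11 at 2.73, PSAT1 at 2.83 and TRIB3 at 3.11. Replicate 3 with NCI-H82 was highest in this group, with ASNS at 835 CPM against 192 and 204 CPM, and the median difference over the list between it and the mean of its other replicates was 1.30 log2 units. Outside the list, ADM2, a peptide hormone gene, and PCK2, a mitochondrial phosphoenolpyruvate carboxykinase, rose by 5.21 ± 0.56 and 3.61 ± 0.43. Without both libraries that stood apart these were 5.20 and 2.86.

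All 24 measured sterol synthesis genes had negative estimates with NCI-H82. Of these, 11 fell and 13 did not pass over all genes, and 24 were lower when adjusted over the list alone. The median log2 fold change was -1.63, with a camera adjusted p of 1.26e-31 and adjusted p = 0.0414 with an estimated correlation. FDFT1 and ACAT2 fell by 1.81 and 2.37 on the log2 scale (adjusted p = 0.0049 and 0.0161). The median difference between replicate 3 and the other replicates with NCI-H82 was -0.82 log2 units over this list.

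Among hypoxia and glycolysis genes, 4 of 23 rose and none fell, and 9 were higher when adjusted over the list alone (median log2 fold change 0.76, camera adjusted p = 1.26e-10, adjusted p = 0.0266 with an estimated correlation). HK2, the gene of a hexokinase, rose by 2.49 ± 0.37 and the angiogenic factor gene VEGFA by 1.87 ± 0.27. Among inflammatory cytokines and NF-kB targets 3 of 25 rose, with CXCL8 at 4.46 ± 0.82, CXCL3 at 4.12 ± 0.77 and TNFAIP2 at 1.42 ± 0.21 (CXCL8 and CXCL3 at 2.93 and 3.24 without both libraries that stood apart), and 7 were higher when adjusted over the list alone (camera adjusted p = 3.37e-10, adjusted p = 0.0514 with an estimated correlation). Of 28 interferon-stimulated genes, MX1 fell by 1.67 (adjusted p = 0.0368), the other members did not pass (OAS3 did with the replicate number as a block, adjusted p = 0.0124), and 9 were lower when adjusted over the list alone (camera adjusted p = 6.47e-10, adjusted p = 0.0593 with an estimated correlation).

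The Notch ligand genes DLL3 and DLL1 fell with NCI-H82, with log2 fold changes of -3.04 ± 0.34 and -2.97 ± 0.43. DLX1 and DLX2, homeobox factor genes, had -2.77 ± 0.35 and -3.21 ± 0.56. Of 22 measured genes on the list of neuroendocrine markers of small-cell lung cancer, 3 fell and none rose (camera adjusted p = 2.05e-06, adjusted p = 0.102 with an estimated correlation). The list median of -0.79 was -0.49 without both libraries that stood apart, and replicate 3 with NCI-H82 deviated by -1.16 log2 units over this list. Other large decreases were those of SMOC1 (-4.96 ± 0.73), IGFL3 (-4.12 ± 0.65), NNAT (-3.32 ± 0.55), HDC (-3.27 ± 0.42), FAM222A (-3.19 ± 0.45) and RGCC (-3.03 ± 0.32).

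All 32 cell cycle genes had negative estimates, with a median log2 fold change of -0.92, and none passed over all genes or adjusted over the list alone (camera adjusted p = 2.28e-11, adjusted p = 0.324 with an estimated correlation). The median difference between replicate 3 and the other replicates with NCI-H82 was -2.82 log2 units over this list. The astrocyte markers GFAP, AQP4 and S100B did not pass. GFAP was at 5052 and 5873 CPM in replicates 1 and 2 but 395 CPM in replicate 3, against 3993 ± 401 CPM alone. BDNF and MYC had estimates of 1.78 ± 0.36 and 1.82 ± 0.47 (adjusted p = 0.0626 and 0.14). C3, a complement component, had 2 counts alone and 157 with NCI-H82, a ratio of 71.0 with a counting interval of 19.3 to 592 (adjusted p = 0.0174).

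The count of 94 genes fell to 9 without replicate 2 and 20 without replicate 1 of astrocytes alone, to 44 and 53 without replicate 2 and replicate 1 with NCI-H82, and to 11 when only these 6 libraries were fitted. With the replicate number as a block it was 196, and BDNF and MYC passed (adjusted p = 0.00622 and 0.0488) while CXCL3 did not (0.0516). INSM1, HES5, HEY1, OLIG1 and GJA1 then passed as lower and ALDH1L1, CXCL6 and BBC3 as higher, with adjusted p from 0.00254 to 0.0498. Without both libraries that stood apart, a setting chosen after seeing the data, it was 420 and held all 94.

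Astrocytes cultured with NCI-H69 had higher levels of inflammatory and hypoxia genes and lower levels of sterol synthesis genes. CLDN11, a tight junction gene (ENSG00000013297.11, chromosome 3, 170418865 to 170454733), rose 239-fold from 1.02 ± 0.718 to 240 ± 52.3 CPM (log2 fold change 7.90 ± 0.48, adjusted p = 4.77e-05). The chemokine gene CXCL8 (ENSG00000169429.10, chromosome 4, 73740506 to 73743716) rose 155-fold to 43.2 ± 2.79 CPM (adjusted p = 0.00165), and DLL3 (ENSG00000090932.10, chromosome 19, 39498895 to 39508481) fell from 52.7 ± 2.75 to 0.515 ± 0.370 CPM (log2 fold change -6.61 ± 0.42, adjusted p = 5.38e-05). In total 831 genes passed, 471 higher and 360 lower, and 2897 had an unadjusted p under 0.05.

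Of 25 inflammatory cytokines and NF-kB targets, 17 rose, none fell and 8 did not pass, and 22 were higher when adjusted over the list alone (median log2 fold change 2.03, camera adjusted p = 6.22e-24, adjusted p = 0.00742 with an estimated correlation). CXCL6, ICAM1 and TNFAIP2 rose by 6.54 ± 0.57, 3.85 ± 0.36 and 4.08 ± 0.23 on the log2 scale. CXCL1 rose to 18.8 ± 14.0 CPM (log2 fold change 6.85 ± 0.80). IL6 did not pass, at 2.33 ± 2.42 CPM alone and 3.23 ± 1.64 CPM with NCI-H69. C3 had 2 counts alone and 971 with NCI-H69, a ratio of 511 with a counting interval of 141 to 4227 (adjusted p = 0.000622). Of 23 reactive astrocyte genes, C3, EMP1 and GBP2 rose, and 5 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0205, adjusted p = 0.169 with an estimated correlation). Without replicate 3 alone and replicate 3 with NCI-H82, which stood apart, 9 of the 25 genes then tested rose and 1 fell.

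Genes that were nearly silent in astrocytes alone included SOST, with 0 counts alone and 501 with NCI-H69, at least 176-fold higher. UBD had 1 count alone and 296 with NCI-H69, a ratio of 312 (counting interval 55.5 to 12350), and PPARG, a nuclear receptor gene, had 2 and 454, a ratio of 239 (65.8 to 1979). PPARG was at 31.2 CPM in replicate 3 with NCI-H69 against 2.46 and 0.810 CPM in the others, and ANGPTL4 at 586 against 67.6 and 89.4 CPM. OR2I1P overlaps UBD and GABBR1 in the annotation, and its 3 counts alone and 309 with NCI-H69 cannot be told apart from reads of UBD, so both genes are uncertain. Reads of VSIR, C3, NNAT, DLL1, PCK2, STRA6, ACAT2, GFAP, IL6, CLDN7, KRT7, MYH11 and MYRF, which overlap other tested genes, carry the same limit where exons are shared.

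Of 24 sterol synthesis genes, 22 fell and 2 did not pass, and 24 were lower when adjusted over the list alone (median log2 fold change -1.78, camera adjusted p = 1.64e-23, adjusted p = 0.0576 with an estimated correlation). HMGCS1 fell from 257 ± 78.3 to 23.8 ± 5.78 CPM (log2 fold change -3.43 ± 0.46), and IDI1 and SQLE had -3.05 ± 0.36 and -2.71 ± 0.28. Of 23 hypoxia and glycolysis genes, 11 rose and none fell, and 16 were higher when adjusted over the list alone (median 1.14, camera adjusted p = 3.84e-13, adjusted p = 0.00742 with an estimated correlation). ADM, BNIP3 and PDK1 rose by 2.78 ± 0.43, 1.91 ± 0.25 and 2.20 ± 0.36. Of the amino acid and unfolded protein stress list, DDIT4 alone passed (1.93 ± 0.34) and ASNS was at 1.40 ± 0.54 (adjusted p = 0.174). With both libraries that stood apart left out, 7 of its 22 genes rose and 1 fell, with ASNS at 1.67 (adjusted p = 0.000368).

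Among neuroendocrine markers, 5 of 22 fell and none rose, and 9 were lower when adjusted over the list alone (camera adjusted p = 6.10e-05, adjusted p = 0.167 with an estimated correlation). These included DLL3, HES6 (-3.92 ± 0.20), INSM1 (-2.18 ± 0.35) and SYP (-2.65 ± 0.47). Of 18 Notch genes 5 fell, and 2 were higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.0158, adjusted p = 0.385 with an estimated correlation). HES5, a Notch target, fell from 34.2 ± 29.9 to 0.109 ± 0.128 CPM, and its spread among astrocytes alone was nearly as large as its mean. Of 16 neural progenitor genes 3 fell, namely HES5, DLX1 and DLX2, and 1 was higher and 8 lower when adjusted over the list alone (camera adjusted p = 0.00354, adjusted p = 0.385 with an estimated correlation). OLIG1 and OLIG2, oligodendrocyte lineage factor genes, had -5.64 ± 0.57 and -2.93 ± 0.33, and HDC, DRD2, PLA2G3 and SEMA3E were also among the largest decreases. HDC had 306 counts alone and 2 with NCI-H69, a ratio of 145 (counting interval 39.9 to 1205).

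Of 25 genes on the list of TGF-beta targets and plasminogen activation, 8 rose, and 8 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00357, adjusted p = 0.385 with an estimated correlation). ID1, SMAD6 and the plasminogen activator gene PLAT were at 3.07 ± 0.42, 2.07 ± 0.25 and 1.31 ± 0.27. Of 19 epithelial and lung lineage genes 5 passed as higher and 0 as lower over all genes, 7 and 4 when adjusted over the list alone, and 10 and 3 without both libraries that stood apart (camera adjusted p = 0.0205, adjusted p = 0.28 with an estimated correlation), among them KRT19, a keratin gene, from 3.39 ± 3.16 to 90.9 ± 35.0 CPM, and ELF3 from 0.293 ± 0.288 to 5.24 ± 0.869 CPM. EPCAM, of the same list, was at 6.41 ± 3.00 CPM alone and 2.06 ± 0.251 CPM with NCI-H69 (adjusted p = 0.0712). GFAP, AQP4, S100B and VIM did not pass, while among astrocyte identity genes ALDH1L1 and ID3 rose (1.46 ± 0.29 and 2.37 ± 0.36) and GJA1 fell (-1.62 ± 0.29). When both libraries that stood apart were left out, AQP4 and S100B passed as lower (-1.92 and -1.23), and 4 astrocyte identity genes rose and 6 fell. All 32 cell cycle genes had negative estimates with NCI-H69 and none passed (camera adjusted p = 6.10e-05, adjusted p = 0.574 with an estimated correlation). Without both libraries 25 passed as lower, with a median of -1.15. That fit kept replicate 3 with NCI-H69, with 10.9% mitochondrial reads, against 12.9% and 10% in the libraries left out. Deviations of this replicate correlated with theirs at 0.338 and 0.307, so the fit is uneven across groups and these calls may depend on it.

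The count of 831 fell to 269 without replicate 2 and 353 without replicate 1 of astrocytes alone, and to 353, 388 and 346 without replicates 1, 2 and 3 with NCI-H69. Without both libraries that stood apart it was 3795 and held all 831.

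Between the co-cultures, amino acid response genes were higher with NCI-H82, and several inflammatory genes and KRT19 were higher with NCI-H69. TRIB3 and CHAC1 were higher with NCI-H82 by 4.03 ± 0.77 and 4.0 ± 0.41 on the log2 scale (adjusted p = 0.0458 and 0.00679), but by 2.41 and 3.42 without both libraries that stood apart. KRT19 was 4.39 ± 1.41 CPM with NCI-H82 and 90.9 ± 35.0 CPM with NCI-H69 (log2 difference -4.36 ± 0.62, adjusted p = 0.0161). In total 136 genes differed, 45 higher and 91 lower with NCI-H82, and 1796 had an unadjusted p under 0.05.

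Of the amino acid and unfolded protein stress list, 8 of 22 were higher with NCI-H82 and none lower (camera adjusted p = 8.62e-13, adjusted p = 0.273 with an estimated correlation), with PSAT1 at 3.03 ± 0.36 and PHGDH at 2.32 ± 0.36. Its median of 1.62 fell to 0.79 without both libraries that stood apart. Of the inflammatory list, 7 of 25 were lower with NCI-H82 and none higher (camera adjusted p = 4.67e-22, adjusted p = 0.0185 with an estimated correlation), with CXCL6 at -3.63 ± 0.46 and ICAM1 at -2.20 ± 0.33. Of 28 interferon-stimulated genes 5 were lower with NCI-H82, all 28 had negative estimates, and 15 were lower when adjusted over the list alone (camera adjusted p = 2.08e-18, adjusted p = 0.0231 with an estimated correlation). Part of this difference lies with NCI-H69, where the list had a median of 0.54 against alone (camera adjusted p = 0.00275, adjusted p = 0.28 with an estimated correlation), 0 members passed and 10 rose without both libraries that stood apart. IFI44L and MX1 differed by -1.84 ± 0.34 and -1.53 ± 0.28. DLL3, HES6 and OLIG1, which were lower in both co-cultures than alone by estimate, were higher with NCI-H82 than with NCI-H69 by 3.56 ± 0.40, 1.88 ± 0.18 and 3.22 ± 0.54. RGS16 differed by 2.84 ± 0.33. Genes lower with NCI-H82 also included ELF3, TNFSF10, GPRC5A, STRA6 and SEMA6B, with differences from -4.28 to -3.31. SPARCL1 and ADAMTS9 were higher with NCI-H82 by 2.06 ± 0.29 and 1.65 ± 0.26, as was VEGFA by 1.65 ± 0.27.

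Without replicate 1 with NCI-H82 the excess of lower genes turned, with 22 higher and 17 lower. It shrank without replicates 2 and 3 with NCI-H82, to 21 and 22 and to 91 and 102. Without replicates 1, 2 and 3 with NCI-H69, 3 and 10, 5 and 11, and 9 and 12 genes were higher and lower. The count of 136 fell to 39 and 43 without replicates 1 and 2 with NCI-H82, to 13, 16 and 21 without replicates 1, 2 and 3 with NCI-H69, and to 76 when only these 6 libraries were fitted. Without both libraries that stood apart it was 927 and held all 136.

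Both co-cultures shared 61 genes changed in the same direction against astrocytes alone, 20 higher and 41 lower, and none passed in opposite directions. CLDN11, CXCL8, VSIR, PADI2 and CEBPB rose in both. VSIR, which encodes an immune checkpoint protein (ENSG00000107738.19, chromosome 10, 71747559 to 71773498), rose from 1.15 ± 0.00721 to 17.8 ± 3.45 and 36.1 ± 10.8 CPM, and PADI2, a peptidylarginine deiminase gene, from 6.04 ± 1.66 to 57.5 ± 5.27 and 146 ± 8.77 CPM. SMOC1, IGFL3, NNAT, HDC and DLX2 fell in both, NNAT from 1678 ± 500 to 168 ± 102 and 59.5 ± 17.1 CPM. Independent lists would share 1.63 higher and 1.14 lower genes, and simulated unchanged groups against shared simulated controls shared 0.05 on average. These simulations drew libraries independently, while the real libraries had correlated deviations, so they may give too little sharing. Across genes the log2 fold changes correlated at 0.695, against 0.502 in simulations, and 71.2% of genes had the same sign against 66.8%. The covariance was 0.417 against a simulated 0.1, a difference of 0.317. Controls of 3 libraries cannot be split into parts of at least 2 each, so part of the excess may come from shared controls. The count fell to 8 and 15 without replicates 2 and 1 of astrocytes alone, 26 and 22 without replicates 1 and 2 with NCI-H82 and 30, 35 and 35 without replicates 1, 2 and 3 with NCI-H69, and was 365 without both libraries that stood apart.

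**Figure D2:**
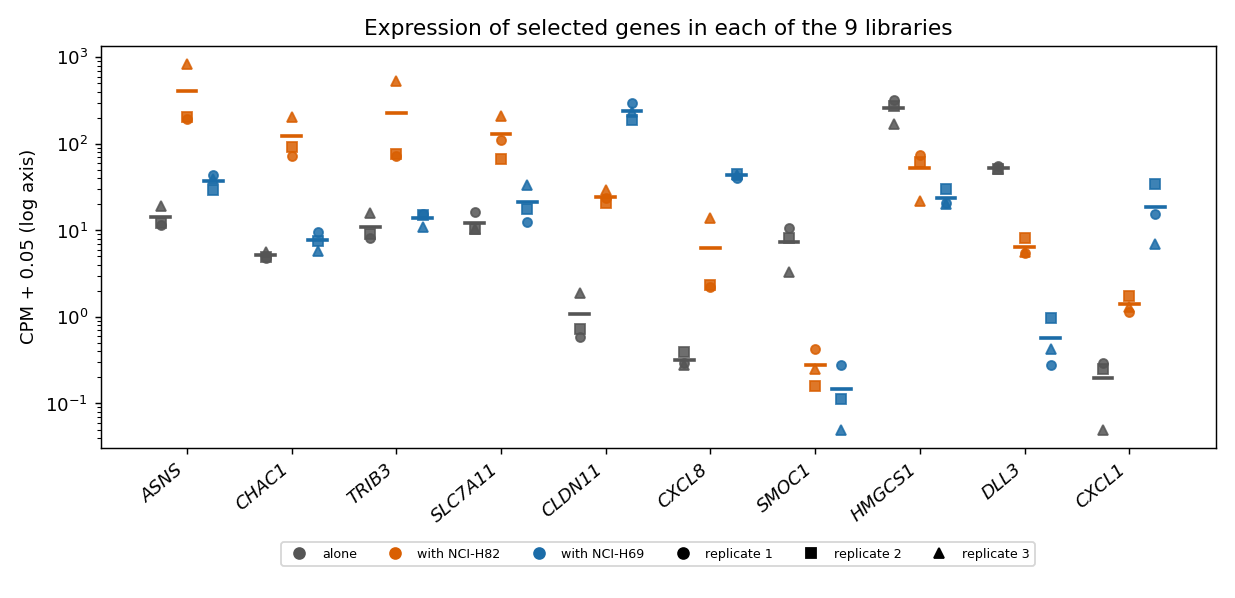
CPM plus 0.05 on a log axis for 10 genes in each of the 9 libraries, with colour for the group, marker shape for the replicate and a bar for the group mean. ASNS, CHAC1, TRIB3 and SLC7A11 are highest with NCI-H82, CLDN11, CXCL8 and CXCL1 are highest with NCI-H69, and DLL3 is lowest with NCI-H69.

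**Figure D3:**
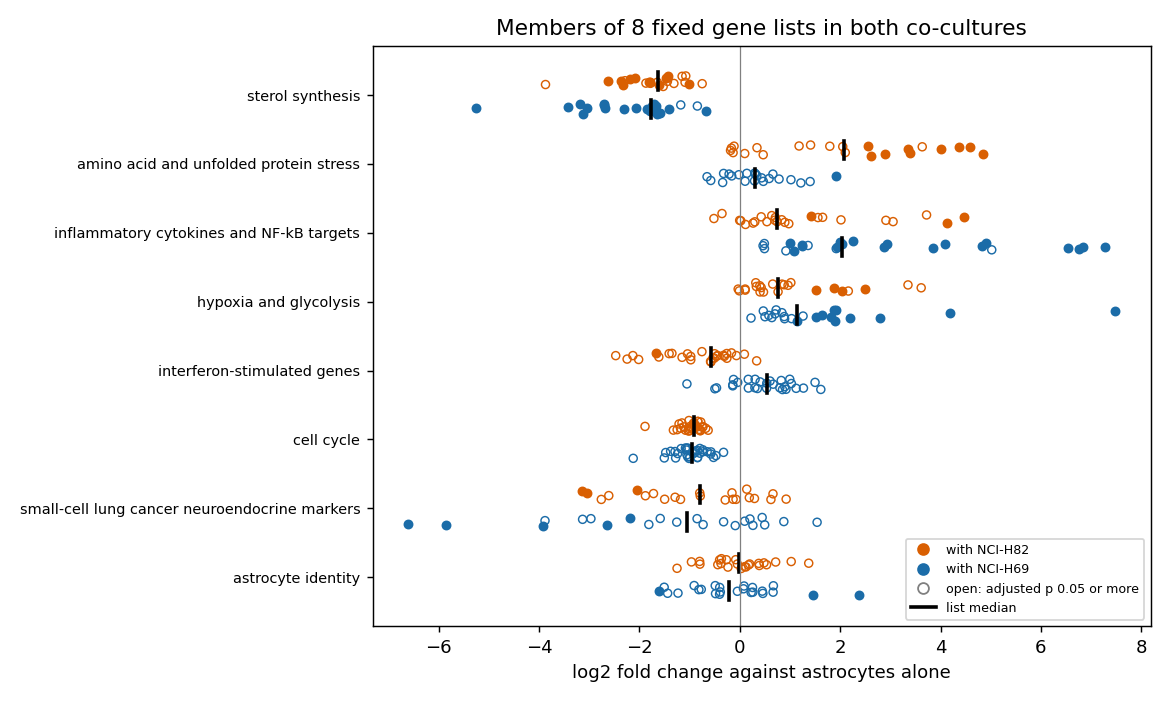
Log2 fold change against astrocytes alone for the members of 8 gene lists, with filled points for members that passed an adjusted p of 0.05, open points for the others and a black bar for the list median. All 24 sterol synthesis genes and all 32 cell cycle genes lie below 0 in both co-cultures.

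In all 94, 831 and 136 genes of the pairwise comparisons the groups did not overlap, and of all genes tested 16.8%, 29.6% and 21.1% did not overlap, where chance gives 10%.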

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

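The tests of the cell type lists, of tumour-cell RNA and of the stress list were chosen only after the results were seen, while the other tests and the regroupings of libraries were set beforehand. The difference between the co-cultures passed its own test for 136 genes. Of 46 genes named in the comparisons against astrocytes alone, 18 passed it. Higher with NCI-H82 among them were ADM2 (3.34 on the log2 scale), ASNS (3.45), C6orf15 (3.58), CHAC1 (4.0), DLL3 (3.56), HDC (3.68), PCK2 (2.76), SEMA3E (3.30), SLC7A11 (2.61), SLC7A5 (2.98) and TRIB3 (4.03). Lower were C3 (-2.78), CLDN11 (-3.29), CXCL1 (-3.79), CXCL6 (-3.63), OR2I1P (-4.99) and UBD (-4.67). HDC had 2 counts with NCI-H69 and 35 with NCI-H82, a ratio of 15 (counting interval 3.86 to 129).

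The same difference passed camera for 9 of 23 lists. Their medians were -0.26 for reactive astrocyte genes, -1.30 for inflammatory genes, -1.28 for interferon-stimulated genes, -0.14 for TGF-beta targets and plasminogen activation, 0.37 for sterol synthesis, -0.48 for hypoxia and glycolysis, 1.62 for amino acid stress, 0.47 for neuroendocrine markers and -1.23 for endothelium. With an estimated correlation 2 of these lists passed, the inflammatory and the interferon-stimulated genes.

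Among 100 splits of the 9 libraries, 1 gave as many genes in the joint test, the real one with 668, and the highest other gave 166. For genes shared by both co-cultures, 1 of 100 splits gave as many, the real one with 61, and the highest other gave 5. The splits stand for no difference among any groups, so they argue against chance for the joint count. For the shared count they cannot decide, because a strong effect of a single co-culture and the shared controls would also set the real split apart. The splits were drawn again under other random states while the script was edited, and the real grouping was highest each time, though 1 earlier draw gave a higher other shared count than 5. The 10 splits of 6 libraries are too few for a share under 0.05. With NCI-H82 against alone the real split gave 11 genes in a fit of these libraries and the highest other 0, with NCI-H69 1180 and 1, and between the co-cultures 76 and 6, with 1 of 10 splits as large in each.

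For list tests the same splits gave a different picture. With NCI-H82 against alone 4 of 10 splits called as many as the real 15 lists and the highest other called 15. Between the co-cultures 8 of 10 called as many as the real 7, with a highest other of 14, and with NCI-H69 against alone 1 of 10 did, 15 against 10. Camera with a preset correlation therefore called lists in wrong groupings of these libraries too. The reason was not tested.

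Replicate 3 of astrocytes alone and replicate 3 with NCI-H82 deviated from their groups together, with a correlation of 0.471 across 14177 genes. After a smooth of transcript length and GC content was removed, the correlation was still 0.418. That smooth took 21.6% and 9.07% of the variance of the deviations. Deviations followed length in both libraries. In replicate 3 alone, genes with the shortest transcripts had a median deviation of 0.527 and those with the longest -0.493. In replicate 3 with NCI-H82 these medians were 0.407 and -0.390. What the smooth captured is thus argued against as the whole cause, but a length or GC bias that it missed stays open. Without mitochondrially encoded and ribosomal protein genes the correlation was 0.461. Those genes are few among 14177, so this shows only that other genes deviated too, and a link to that share stays open. The lists of oligodendrocyte lineage and mural cells had medians of at most -0.196 in both libraries, with every upper 95% bootstrap limit at 0.289 or lower. These markers thus showed no rise. The bootstrap drew genes within each library, and a wider shift of that library could hide added RNA, so the question is not decided. The bound for these limits was restated after the values were seen. RNA of neurons or endothelium stays open, since their medians of at most -0.298 reach upper limits of 0.918 and 0.513 in the replicate alone. In the NCI-H82 replicate their medians were -1.45 and -1.33, with upper limits of -0.775 and -0.0525, both under 0. RNA of epithelial cells also stays open, with a median of 0.491 in the replicate alone (95% bootstrap interval 0.0327 to 1.52). Its list median was -0.0493 in the NCI-H82 replicate. Replicate 3 with NCI-H69 deviated in part like these libraries, with correlations of 0.338 and 0.307, and had the highest mitochondrial share of its group, 10.9%. What the libraries numbered 3 share is not given in the labels and was not tested. RNA degradation or a difference in culture was not tested, and no group of the design gives a biological explanation.

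Tumour-cell RNA could raise epithelial or inflammatory genes in a co-culture. Of 37 neuroendocrine list genes, 13 were under 0.5 CPM in astrocytes alone, and 0 of the 13 reached 1 CPM with NCI-H69 and 0 with NCI-H82, where the highest were 0.264 and 0.724 CPM. Members that astrocytes alone also expressed went both ways by estimate, with DLL3 and INSM1 lower in both co-cultures. UCHL1 was at 238 CPM alone, 452 CPM with NCI-H82 and 324 CPM with NCI-H69, and SNAP25 at 1.65, 0.941 and 4.81 CPM. The highest count of UCHL1 in any library was 4167 alone, 13961 with NCI-H82 and 5348 with NCI-H69, so 1 library carried much of its NCI-H82 mean. Without both libraries that stood apart, 2 list members passed as higher and 12 as lower with NCI-H69. No library measured the tumour lines alone, so these values bound no share of tumour-cell RNA, which stays open. A response of astrocytes to the tumour lines, the difference the design names, was not tested apart from this.

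Amino acid response genes were higher with NCI-H82. The libraries that stood apart are argued against as the whole cause, since 12 list members passed without them against 9 with them, but they carry part of its size, as the list median fell from 2.08 to 1.34. An unfolded protein response as part of the same change stays open. The 10 members on the unfolded protein side of the list, among them HSPA5 and XBP1, had a median log2 fold change of 0.22. Its 95% bootstrap interval was -0.14 to 1.18, while the 12 other members had a median of 3.37. The bound for this test was restated with the interval after its value was seen, and the earlier bound of 0.25 would have argued against it. Nutrient depletion by the tumour cells was not tested.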

How the results depend on the processing

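A pair of fits were chosen after seeing the data, the one without both libraries that stood apart and limma voom with quality weights, and all others were fixed beforehand. Counts are given in the order of joint test, NCI-H82 against alone, NCI-H69 against alone, between co-cultures and shared, with 668, 94, 831, 136 and 61 as reported. DESeq2 gave 1629, 481, 1650, 561 and 324. With the replicate number as a block they were 1030, 196, 1370, 205 and 155, and not every library correlated best with its own number. Without both libraries that stood apart they were 2960, 420, 3795, 927 and 365, and quality weights gave 4951, 2132, 4857, 1252 and 1544. The former fit kept replicate 3 with NCI-H69, at 10.9% mitochondrial reads, and so was uneven across groups. No low-count filter moved NCI-H82 against alone to 193 and the shared count to 125. A transcript length offset moved the co-culture difference to 72 and the shared count to 40. Fits of only the groups compared gave 11 with NCI-H82 and 76 between the co-cultures. The causes were not tested. RLE and upper-quartile factors, the stricter filter, protein-coding genes alone, removal of mitochondrial genes and a log2 fold change of at least 1 moved no count by over 1.5 times.

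Leaving out 1 replicate gave 207 to 1203 genes in the joint test, 9 to 142 with NCI-H82, 269 to 932 with NCI-H69, 13 to 193 between the co-cultures and 8 to 117 shared. The joint count was 257 and 207 without replicates 1 and 2 alone, 1203 without replicate 3 with NCI-H82, and 229, 238 and 262 without replicates 1, 2 and 3 with NCI-H69. Without replicate 3 alone the NCI-H82 count was 61, and without replicate 3 with NCI-H82 it was 142 and the shared count 117.

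Some list tests that had not passed did so in the other direction of the camera test, and no call reversed. Without replicate 3 with NCI-H82, astrocyte identity turned upward with NCI-H82 against alone (camera adjusted p = 0.0206) and against NCI-H69 (0.00512), and the cell cycle list against NCI-H69 (3.38e-05). Without both libraries that stood apart, astrocyte identity, cell cycle and extracellular matrix turned upward against NCI-H69 (0.00428, 5.57e-05 and 0.0388). The highest p with any replicate left out was 0.535 for astrocyte identity with NCI-H82 against alone, and 0.753 and 0.694 for astrocyte identity and cell cycle between the co-cultures. Over all alternatives, 716 list tests stayed on their side of the threshold, called or not, 79 lost a call, 27 gained one and 6 gained one in the other direction. For named genes 5221 kept their side of the threshold, 437 lost it, 412 gained it and 0 reversed. At this depth and spread, 2-fold changes were mostly missed in simulated data.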

Other observations

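The retinoid genes among the largest changes were chosen only after the results were seen, while the tests of the lists and of the other retinoid genes were set beforehand. With NCI-H82, the count of higher and lower genes was 1 and 0 of 23 reactive astrocyte genes, 1 and 0 of 36 secreted factors, 0 and 0 of 25 TGF-beta target and plasminogen activation genes, 0 and 0 of 32 matrix genes, 1 and 0 of 19 proteases and inhibitors, 0 and 0 of 20 p53 targets, 1 and 0 of 14 oxidative stress genes, 0 and 1 of 18 Notch genes and 0 and 2 of 16 progenitor genes. Without both libraries that stood apart they were 2 and 1 for reactive astrocyte genes and 3 and 0 for secreted factors. TGF-beta target and plasminogen activation genes then had 4 and 0, matrix genes 1 and 1, proteases and inhibitors 1 and 1 and p53 targets 2 and 1. Oxidative stress genes had 2 and 0, Notch genes 0 and 5 and progenitor genes 0 and 3. The protease inhibitor gene TIMP3 rose by 1.73 ± 0.31 on the log2 scale over all 9 libraries. With NCI-H69, the counts over all 9 libraries were 0 and 1 for secreted factors, 2 and 1 for matrix genes, 1 and 2 for proteases, 3 and 0 for p53 targets and 3 and 0 for oxidative stress genes. Without both libraries that stood apart they were 6 and 7, 2 and 8, 2 and 5, 8 and 1 and 9 and 0 in this order. The metallothionein gene MT2A rose by 2.76 ± 0.36, the p53 target BBC3 by 2.31 ± 0.35 and the cathepsin gene CTSB by 1.59 ± 0.36, while ADAM12 fell to 95.2 from 361 CPM.

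Markers of other cell types moved in both directions with NCI-H69. Of 11 oligodendrocyte lineage genes 2 rose, CLDN11 and MYRF, and 3 fell. Of 6 endothelial genes 2 rose, with KDR at 2.54 ± 0.46, of 16 mural and fibroblast genes 2 fell, with MYH11 at -2.67 ± 0.40, of 2 measured microglial genes CD68 rose (2.03 ± 0.33), and of 13 neuronal genes none passed. Leaving out both libraries that stood apart, higher and lower counts were 2 and 6 of oligodendrocyte lineage, 5 and 0 of endothelial, 0 and 8 of mural and fibroblast and 1 and 5 of neuronal genes. With NCI-H82, OLIG2 fell (-1.78 ± 0.31) and CLDN11 rose, and no endothelial, mural, microglial, neuronal or epithelial list gene passed, while KDR, CLDN7 and KRT7 passed with the replicate number as a block. Without both libraries that stood apart, higher and lower counts with NCI-H82 were 4 and 0 of 19 epithelial, 1 and 0 of 6 endothelial and 1 and 3 of 11 oligodendrocyte lineage genes. They were 0 and 1 of 16 mural and fibroblast and 0 and 1 of 13 neuronal genes.

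Retinoid genes drew attention among the largest changes with NCI-H69, where the retinol receptor gene STRA6 was at 5.29 ± 0.70, the retinaldehyde reductase gene DHRS3 at 4.30 ± 0.37 and CYP26B1, of retinoic acid breakdown, at 6.42 ± 1.14. LRAT and TGM2 had also been seen. LRAT did not pass (1.19 ± 0.36, adjusted p = 0.0889) and TGM2 did (3.93 ± 0.30, adjusted p = 0.000178). A candidate explanation is a response to retinoic acid. Of 24 other retinoid genes listed before their values were seen, 16 were measured, and 6 rose and 1 fell with NCI-H69. The gene that fell was HOXB2 (-1.14 ± 0.28, adjusted p = 0.0454). None of 10000 random sets matched on expression held as many higher genes, a share of 1e-04 that is the smallest they can give, and their median was 0. The retinoic acid receptor gene RARB rose by 2.96 ± 0.34 (adjusted p = 0.00153) and RARRES1 by 3.29 ± 0.54 (adjusted p = 0.00819), while CYP26A1, a direct target, was at 0.46 ± 0.57 (adjusted p = 0.725). Genes in such a set are not independent, and other regulators of these genes were not tested, so this remains a hypothesis.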
